A study of Homo sapiens with 7 samples.

How the data were processed

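ChIP-seq libraries of ERα (antibody H-20) and c-Jun (antibody H-79) from MCF-7/c-Jun-Tet cells were used, 1 library for each antibody after vehicle, 10 nM E2 or 1 µM tamoxifen for 1 h, fixed with 1% formaldehyde for 10 min. Groups were taken from the sample labels. The series has 7 samples, of which 6 have a peak list and 1 is the input DNA. No group has a replicate, so no test between treatments was made.

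Reads were processed with CASAVA 1.8, Bowtie 0.12.9 and HOMER (version not given in the sources used here) on build hg19, per the submitters' processing notes. Peaks were called per library with MACS 2.1.0.20140616, per the file headers, with fragments extended to 200 bp without a fitted model, a q cutoff of 0.05, 1 tag kept per position and strand, tags of 51 bp, an effective genome of 2.7 Gb and the same single input for all lists. Each deposited list gives a position, the pileup signal at the summit (coverage by extended fragments), a fold ratio over input and the −log10 of p and q for each peak, all computed by the authors' caller per the file headers. The pileup column held whole numbers in all lists, and with 1 tag kept per position and strand it cannot exceed 400. Total tags in M (mega) were 25.1 M, 29.6 M and 29.0 M for ERα and 29.4 M, 34.3 M and 36.6 M for c-Jun in vehicle, E2 and tamoxifen. Tags after filtering were 23.1 M, 26.0 M, 25.7 M, 27.1 M, 31.0 M and 32.9 M in the same order, and 42.3 M for the input.

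From these files the following were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures drawn in matplotlib 3.10.9. Peaks on chromosomes 1 to 22 and X were used, and others were counted separately. Pileups were scaled to 10 M filtered tags. The local input level was recovered from the authors' pileup and fold, as (pileup + 1) / fold - 1, and divided by the genome-wide background of the library. The caller's p was recomputed from the 2 values as a Poisson tail, with a median absolute difference of at most 6.26e-06 in −log10 p. Peaks with input at least 3 times background are called high input. The fold and p of a peak are the authors' and serve to describe, filter and rank peaks within a list.

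Peaks were shared when they overlapped by at least 1 bp. Shares have exact Clopper-Pearson 95% intervals, which treat peaks as independent and cover counting error only. As background, each list was shuffled 100 times within the span of peaks of each chromosome, and shifted once by 50 kb, which keeps local clustering. For pileup ratios each peak was paired with the highest peak overlapping it in the other list, and log2 ratios were summarised by median and quartiles. In the analyses of ERα change by c-Jun, only pairs that were each other's highest partner were kept. Regions were merged over all lists where peaks overlapped. Peaks were divided into 5 equal groups by the caller's p. Differences of shares have normal 95% intervals.

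The overlap code was tested on simulated lists: for 5000 peaks with 3 planted shares it found 7500 of 7500 planted overlaps, and 8 of 8 counts from the real lists equalled those of bedtools 2.31.1. In simulated data for the E2 lists, thinning to vehicle depth gave 100.2% (31598 ERα peaks) and 100.5% (24158 c-Jun peaks) of the calls obtained by drawing at that depth. The interval of a difference of shares covered the true difference in 94.45% of 2000 simulated draws.

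The comparisons of peak numbers, overlaps and pileups, their alternatives and the rule for named peaks were fixed before the data were examined. That plan assumed normalised tag counts, while the lists hold the caller's pileup, so the pileup per 10 M filtered tags was used in their place. Divisions of lists by strength, fold cutoffs other than 8, the highest peaks of a list, windows of input, and classes of ERα peaks unique to 1 ligand were chosen after the data were seen. The rule names the 5 highest peaks by pileup per 10 M tags of each class (vehicle and treated, treated alone, vehicle alone, both factors), by position. The alternatives, applied to both lists of an overlap, were peaks of at least 8-fold over input, leaving out chromosomes 1, 17 and 20, leaving out the 1% of peaks with the highest input, matched list lengths, 50% reciprocal overlap, centres within 100 bp, and centring of pileup ratios. Further alternatives were added after seeing the data: a common p threshold, only peaks with input under 3 times background, all 6 lists at one length, one c-Jun list for both classes of ERα peaks, and ranking by fold over input. Distances to transcription start sites, motif shares and gene list counts were planned but not run, because no hg19 genome or annotation was at hand and the gene table at hand is of build GRCh38.p14. Peaks therefore carry positions and no gene names, and exon, intron and promoter classes are not given.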

Results

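Binding of the estrogen receptor ERα and of c-Jun was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in MCF-7/c-Jun-Tet cells. MCF-7 is an ERα-positive human breast cancer line, and c-Jun is a subunit of the AP-1 transcription factor. The derivative used here carries c-Jun under tetracycline control by its name, was grown without tetracycline, and is described in the series title as overexpressing c-Jun. No parental MCF-7 library was among the samples used here, so the values describe ligand treatments within c-Jun cells and not the effect of c-Jun itself. Cells were kept in steroid-depleted medium for 72 h and then given ethanol vehicle, 10 nM 17β-estradiol (E2, the natural ERα agonist) or 1 µM tamoxifen (a selective ERα modulator used against this cancer) for 1 h. Each of the 6 combinations of antibody and treatment was 1 library, and 1 input DNA library served all 6. The doses of the ligands differ, so each comparison of tamoxifen with E2 is also a comparison of 1 µM with 10 nM.

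After removal of duplicates the ERα libraries held 23.1 M (mega) tags in vehicle, 26.0 M in E2 and 25.7 M in tamoxifen. The c-Jun libraries held 27.1 M, 31.0 M and 32.9 M in the same order, and the input held 42.3 M. With 1 library per group no difference between treatments had a replicate check, and no p-value between treatments is given. Intervals of shares are exact binomial 95% intervals over peaks, those of differences between shares are normal 95% intervals, and both cover counting error only. Positions are hg19 coordinates on chromosomes 1 to 22 and X.

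The first comparison addressed how each ligand changed ERα binding. ERα was detected at 5955 sites in vehicle, at 31598 sites in E2 and at 33717 sites in tamoxifen, which was 5.31 and 5.66 times the vehicle number at 1.12 and 1.11 times its tags. The ratios to vehicle were larger for peaks of at least 20-fold over input, which numbered 380 in vehicle, 4733 in E2 and 4564 in tamoxifen. These counts include sites already called in vehicle at a lower fold. Peaks shared by vehicle and E2 had a median fold of 6.90 in vehicle and 25.9 in E2. The treated lists held most of the vehicle set and many further sites, which with 1 library each can reflect the ligand or a weaker vehicle library. Of the vehicle peaks, 93.2% (92.5 to 93.8%) overlapped an E2 peak and 93.2% (92.6 to 93.9%) a tamoxifen peak, against 0.768% and 0.828% for shuffled positions and 2.42% and 2.35% for positions shifted by 50 kb. The 406 vehicle peaks missing from the E2 list had a median fold over input of 2.51, and 67.7% of them lay where the input was at least 3 times its genome-wide background.

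**Figure D1:**
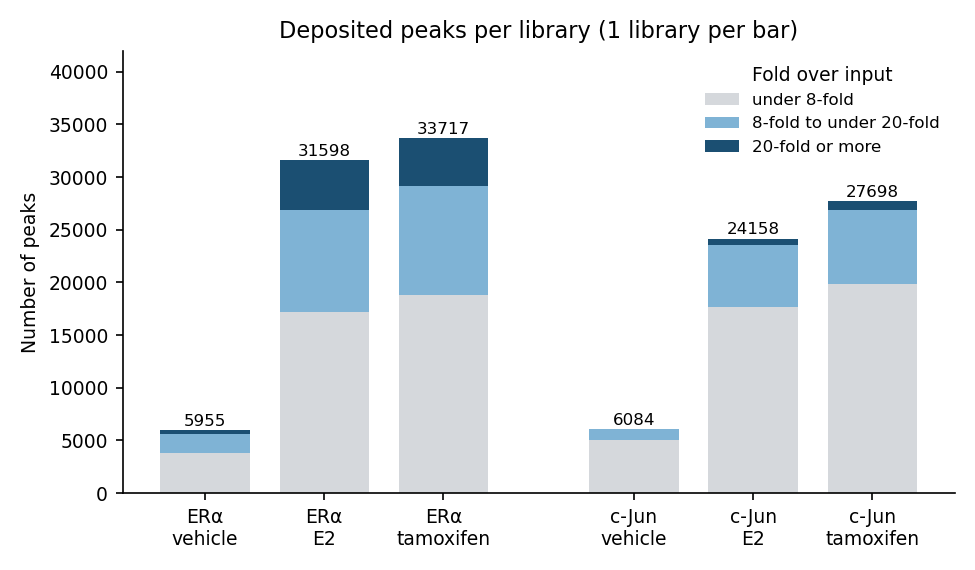
Number of deposited peaks (vertical axis) in each of the 6 libraries, divided by the authors' fold over input. The vehicle libraries hold 5955 ERα and 6084 c-Jun peaks, and the treated libraries hold between 24158 and 33717.

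Sites already occupied in vehicle were the strongest sites after treatment. E2 peaks that overlapped a vehicle peak had a median fold over input of 25.9 (quartiles 15.3 and 42.7), while the 26150 others had a median of 6.495 (4.90 and 9.77). All 300 of the highest E2 peaks with input under 3 times background overlapped a vehicle peak (98.8 to 100%), as did 98.9% (98.0 to 99.4%) of the highest 1000 and 44.1% (43.1 to 45.1%) of the highest 10000. At 5448 E2 peaks shared with vehicle the pileup at the summit per 10 M tags was a median 3.25 times higher in E2 (log2 ratio 1.70, quartiles 1.25 and 2.14), and at 5457 tamoxifen peaks it was 3.29 times higher in tamoxifen (log2 ratio 1.72, quartiles 1.38 and 2.02). These ratios leave out the gained sites, which have no vehicle value, and understate the change at the highest sites because removal of duplicates caps the pileup at 400.

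By the rule fixed for naming, the highest ERα peaks held by vehicle and E2 were chromosome 17 from 59800472 to 59800984, and on chromosome 20 from 46704304 to 46705410, 49343667 to 49344658, 49380338 to 49381253 and 52739989 to 52740704. All 5 reached the cap of 400, but their input was 14.7 to 25.2 times background and their fold over input only 8.09 to 13.7. Of the 5 highest E2 peaks absent from vehicle, 3 were also on chromosome 20 in such input, at 24.2 to 32.2 times background. The exception with low input was chromosome 19 from 55718504 to 55718967, at 59.7-fold over input, with a pileup per 10 M tags of 93.1 in E2 and 19.8 in tamoxifen. The matching tamoxifen peak was chromosome 20 from 36773376 to 36773812, at 74.5-fold over input, with a pileup per 10 M tags of 99.0 in tamoxifen and 34.6 in E2. The 5 highest vehicle peaks absent from E2 lay on chromosome 16 between 46386660 and 46405949 and on chromosome 2 from 92313319 to 92313536, with folds of 1.48 to 1.75 over an input of 81.7 to 111 times background.

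Ranked instead by fold over input, a ranking chosen after the values were seen, the leading sites held by vehicle and E2 had input at background. The ERα peak on chromosome 10 from 95194736 to 95195407 reached 133-fold in E2, with a pileup per 10 M tags of 77.0 in vehicle, 149 in E2 and 139 in tamoxifen. The peak on chromosome 11 from 20052717 to 20054093 had 62.3, 147 and 136 in the same order. The peak on chromosome 17 from 38477994 to 38479218 had 90.8, 136 and 131.

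The second comparison set tamoxifen beside E2 for ERα. Both ligands filled largely one set of sites at nearly one level. Of the E2 peaks 77.9% (77.4 to 78.3%) overlapped a tamoxifen peak, and of the tamoxifen peaks 72.8% (72.4 to 73.3%) overlapped an E2 peak, against 0.855% and 0.798% for shuffled positions. At 24559 shared peaks the median log2 ratio of tamoxifen to E2 was 0.04 (quartiles -0.33 and 0.41). Single sites spread around it, with 4.01% over 2-fold higher in tamoxifen and 5.70% over 2-fold higher in E2. Most peaks called with 1 ligand alone were weak, with median folds of 4.92 for the 6993 E2 peaks and 4.94 for the 9158 tamoxifen peaks. Among peaks of at least 20-fold, 9 of 4733 E2 peaks had no tamoxifen partner and 3 of 4564 tamoxifen peaks had no E2 partner. Those 3 were chromosome 2 from 121822607 to 121822960, and chromosome 5 from 6742994 to 6743399 and from 51156308 to 51156750. By the rule fixed for naming, the 5 highest peaks by pileup in each of these classes lay on chromosomes 2, 10, 16 and 17 at folds of at most 1.75 over input of at least 60.9 times background.

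**Figure D2:**
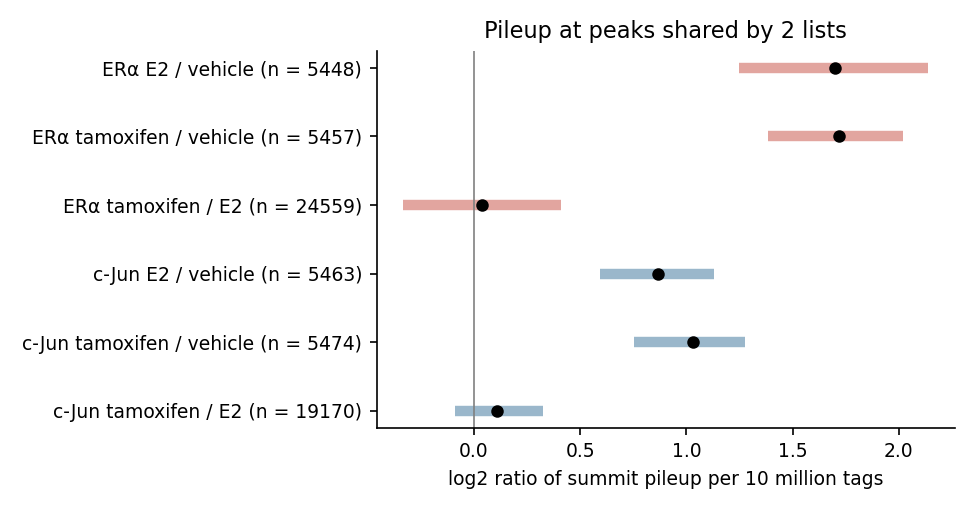
Log2 ratio of summit pileup per 10 M tags between 2 lists of one antibody (horizontal axis), over the peaks they share. Points are medians and bars run between the quartiles over n peaks. The ratios to vehicle are higher for ERα (1.70 and 1.72) than for c-Jun (0.87 and 1.03), and both tamoxifen to E2 ratios lie near 0.

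The third comparison addressed c-Jun binding. c-Jun was detected at 6084 sites in vehicle, 24158 in E2 and 27698 in tamoxifen, or 3.97 and 4.55 times the vehicle number at 1.14 and 1.21 times its tags. Peaks of at least 20-fold over input numbered 17 in vehicle, 555 in E2 and 854 in tamoxifen. As for ERα, the vehicle set was kept: 90.7% (89.96 to 91.4%) of vehicle peaks overlapped an E2 peak and 90.9% (90.2 to 91.6%) a tamoxifen peak. Pileup at shared peaks was a median 1.82 times higher in E2 (log2 ratio 0.87, quartiles 0.59 and 1.13) and 2.04 times higher in tamoxifen (log2 ratio 1.03, quartiles 0.75 and 1.27). These medians were lower than those of ERα.

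E2 and tamoxifen gave closely similar c-Jun sites. Of the E2 peaks 79.6% (79.1 to 80.1%) overlapped a tamoxifen peak, and of the tamoxifen peaks 69.2% (68.7 to 69.8%) overlapped an E2 peak. At 15-fold over input or more no c-Jun peak was called with 1 ligand alone, among 1489 E2 and 2016 tamoxifen peaks. Over 19170 shared peaks the median log2 ratio of tamoxifen to E2 was 0.11 (quartiles -0.09 and 0.33), and 63.6% of the peaks were higher in tamoxifen. That ratio was -0.03 after centring on the peaks held by all 3 c-Jun lists. Examples of strong c-Jun sites, again chosen by fold after the values were seen, were chromosome 16 from 29276619 to 29277094, with a pileup per 10 M tags of 28.4 in vehicle, 55.6 in E2 and 59.2 in tamoxifen, and chromosome 2 from 102844059 to 102844795, with 29.9, 53.0 and 59.2. By the rule fixed for naming, 4 of the 5 highest c-Jun peaks held by vehicle and E2 lay on chromosomes 1, 6 and 7 at a fold of 1.35 to 1.37 over input of at least 125.8 times background, and the remaining peak was chromosome 20 from 49377814 to 49379670 at 8.18-fold.

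**Figure D3:**
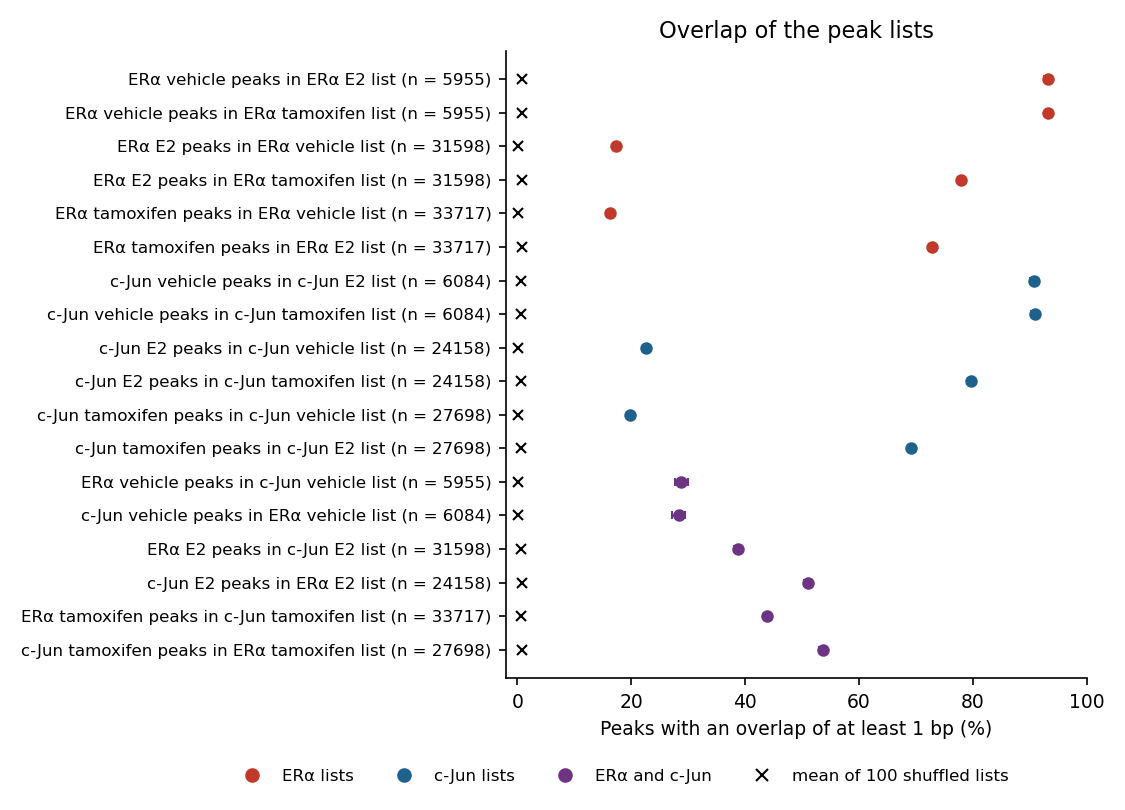
Share of the peaks of 1 list that overlap another list by at least 1 bp (horizontal axis, %), with exact 95% binomial intervals over n peaks and the mean of 100 shuffled lists as crosses. Vehicle peaks are nearly all in the treated lists (90.7 to 93.2%), and ERα and c-Jun lists overlap far above the shuffled level.

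The fourth comparison asked where ERα and c-Jun were found together. In vehicle 28.8% (27.6 to 29.95%) of ERα peaks overlapped a c-Jun peak, in E2 38.7% (38.1 to 39.2%) and in tamoxifen 43.8% (43.3 to 44.4%), against 0.153%, 0.604% and 0.690% for shuffled positions and 0.571%, 1.33% and 1.46% for positions shifted by 50 kb. Of the c-Jun peaks 28.3% (27.2 to 29.5%), 51.0% (50.3 to 51.6%) and 53.6% (53.0 to 54.2%) overlapped an ERα peak in the same order. The summits of the overlapping peaks lay close together, a median 38 bp apart in E2 and 37 bp in tamoxifen. Longer lists overlap more often, and with all 6 lists held to the 5955 peaks of best p the ERα share with c-Jun was 28.3% in vehicle, 31.6% in E2 and 31.6% in tamoxifen, and the c-Jun share with ERα was 28.5%, 31.7% and 31.8%. With both lists cut at 8-fold over input, so that a partner also had to reach 8-fold, the ERα share was 7.72%, 21.99% and 25.8% and the c-Jun share was 15.9%, 48.7% and 49.1%.

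With either ligand, co-occupied sites were the stronger sites of both factors. The median fold over input of c-Jun peaks with and without ERα was 6.56 and 5.10 in E2 and 6.66 and 5.15 in tamoxifen, but 5.53 and 5.57 in vehicle. In E2 the share of ERα peaks with c-Jun was 22.8% (21.8 to 23.9%) in the weakest of 5 equal groups of the list and 66.1% (64.9 to 67.2%) in the strongest, and in tamoxifen it was 30.5% (29.4 to 31.6%) and 70.4% (69.3 to 71.5%). In vehicle the same shares were 22.2% (19.8 to 24.6%) and 35.7% (33.0 to 38.5%). Of ERα E2 peaks also held by vehicle, 75.3% (74.1 to 76.4%) overlapped a c-Jun E2 peak, against 31.0% (30.5 to 31.6%) of the E2 peaks gained. The peaks held by vehicle were also stronger, at a median fold of 25.9 against 6.495. No comparison at equal strength was made, so the 2 cannot be told apart here. In vehicle itself, with its shorter c-Jun list, c-Jun was called at 30.9% (29.7 to 32.2%) of the E2 peaks held by vehicle.

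**Figure D4:**
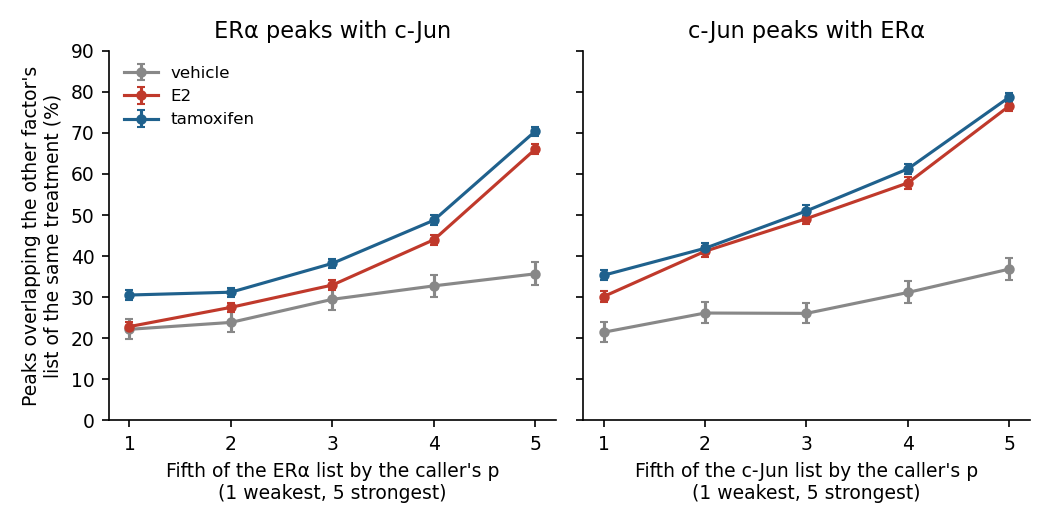
Share of ERα peaks that overlap c-Jun (left) and of c-Jun peaks that overlap ERα (right) in the list of the same treatment (vertical axis, %), by group of the list cut in 5 and ranked by the caller's p (horizontal axis). Bars are exact 95% binomial intervals. In E2 the ERα share rises from 22.8% to 66.1%, and in tamoxifen from 30.5% to 70.4%.

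Merging all lists gave 55890 regions, of which 23254 held ERα alone, 15272 held c-Jun alone and 17364 held both, though not always in the same treatment. The largest class, 10236 regions, held ERα in E2 and tamoxifen with no other call. A further 4124 regions held both factors with both ligands and neither in vehicle, and 1616 regions were in all 6 lists. In a comparison chosen after the values were seen, ERα peaks unique to 1 ligand overlapped c-Jun less often than shared ones. The unique peaks were also weaker, with median folds of 4.92 in E2 and 4.94 in tamoxifen against 8.89 for shared E2 peaks. Unique and shared peaks were not compared at equal strength, so class and strength cannot be told apart here. c-Jun tamoxifen peaks overlapped 26.1% (25.2 to 27.0%) of ERα peaks unique to tamoxifen, c-Jun E2 peaks overlapped 16.2% (15.3 to 17.1%) of those unique to E2, and among ERα E2 peaks shared with tamoxifen the c-Jun E2 share was 45.1% (44.4 to 45.7%). The difference of 9.86 percentage points (8.62 to 11.1) between the classes unique to 1 ligand was 3.65 points (2.46 to 4.84) with the c-Jun E2 list used for both, -0.54 points (-1.15 to 0.07) with the c-Jun vehicle list used for both, and 1.64 points (-0.02 to 3.29) with all lists cut at 8-fold over input. That last setting redefines the classes, since an ERα peak counts as unique when its partner is under 8-fold: it holds 2864 E2 and 3404 tamoxifen peaks, while 561 and 553 peaks of at least 8-fold had no partner at all.

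Among windows of 1 Mb with a median input at the peaks under 2 times background, ERα binding was densest on chromosome 16 from 85000001 to 86000000. This window held 18 ERα peaks in vehicle, 79 in E2 and 60 in tamoxifen, and 13, 39 and 49 c-Jun peaks. The window on chromosome 8 from 134000001 to 135000000 held 11, 54 and 58 ERα peaks and 18, 44 and 46 c-Jun peaks. In 27 of 1959 windows of 1 Mb with at least 20 peaks, the input at the peaks was at least 5 times background. Of these, 8 were on chromosome 20 and 4 on chromosome 17. On chromosome 20 from 52000001 to 53000000 the median input was 22.1 times background, and on chromosome 17 from 59000001 to 60000000 it was 17.2 times. The labels conflict on the origin of the input, which one field assigns to T47D, another breast cancer line, and another field to MCF-7. All 6 lists were called against this input, so every fold over input, p and input level given here depends on which line it came from.

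**Figure D5:**
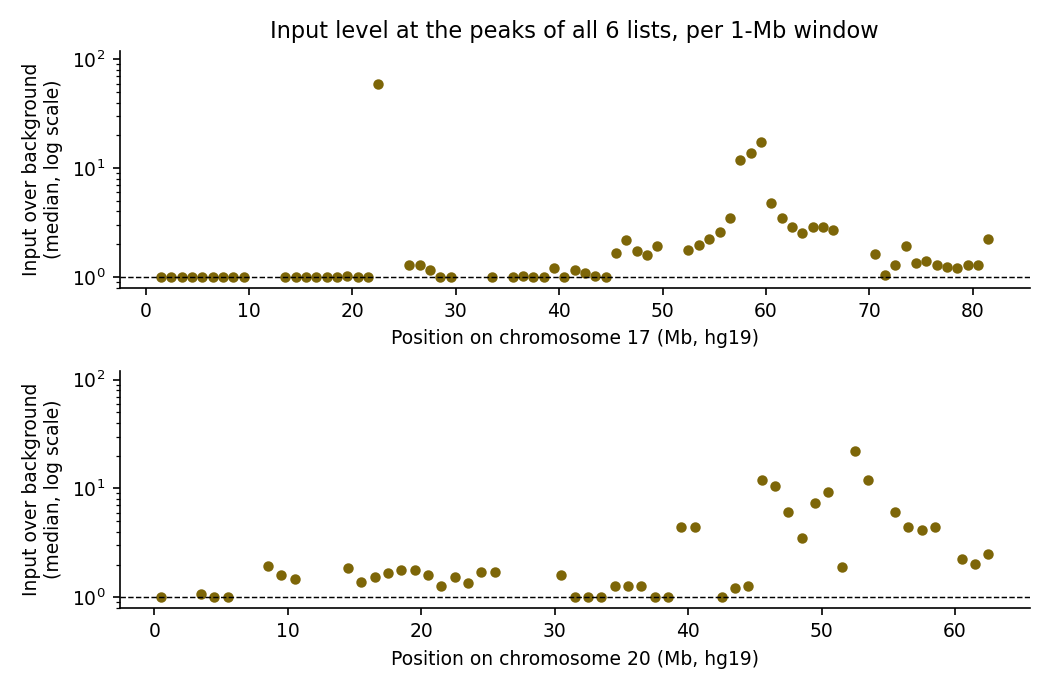
Median input at the peaks of all 6 lists over its genome-wide background (vertical axis, log scale) along chromosomes 17 and 20 (horizontal axis, Mb, hg19). Each point is a 1-Mb window with at least 20 peaks, and the dashed line is background. Input reaches 17.2 times background on chromosome 17 and 22.1 times on chromosome 20, apart from 1 window on chromosome 17 at 59.1 times.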

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

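Several of the tests below were chosen only after the result was seen. They are those of the longer c-Jun tamoxifen list, the other c-Jun lists, low input and the fold cutoffs of 10, 15 and 20. The 8-fold cutoff and the matched list lengths for the classes unique to 1 ligand were also chosen then.

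Peaks outside chromosomes 1 to 22 and X were left out of every comparison, and are given here because data that no comparison used held more than the 3 peaks that a count of 0 allows. For ERα they numbered 115 in vehicle, 187 in E2 and 193 in tamoxifen, and for c-Jun 118, 149 and 103. Of these, 33, 39 and 44 for ERα and 34, 42 and 20 for c-Jun lay on the unplaced sequence Un_gl000220. The mitochondrial counts were 1, 3, 2, 1, 1 and 1. No explanation for these counts was tested.

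The number of peaks of at least 20-fold over input moved in opposite directions from E2 to tamoxifen for the 2 antibodies. The ratio of tamoxifen to E2 was 0.964 for ERα and 1.54 for c-Jun. The opposite directions were absent at the lower cutoffs counted: ERα peaks in tamoxifen and E2 numbered 14900 and 14372 at 8-fold, 11431 and 11038 at 10-fold and 6900 and 6828 at 15-fold. Cutoffs above 20-fold were not counted. Each ratio rests on 1 library per treatment, and the difference between them was not tested.

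The vehicle lists are far shorter than the treated lists for both antibodies. Thinning the E2 libraries to vehicle depth left a median of 31175.5 ERα and 23738.5 c-Jun peaks, against 5955 and 6084 in vehicle, so depth was not the cause. A simulated drop of enrichment by one factor at every site, 0.285 for ERα and 0.511 for c-Jun, left 13862.5 and 14937.5 peaks, still 2.33 and 2.46 times the vehicle lists. Those factors come from peaks called in vehicle, which favours sites that kept their signal, so a stronger uniform drop and a drop that differs among sites could not be told apart. An effect of the ligand on binding and a vehicle chromatin preparation of lower quality for both antibodies cannot be separated with 1 library each.

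ERα peaks unique to tamoxifen held c-Jun more often than those unique to E2, by 9.86 points. The difference was 3.65 points (2.46 to 4.84) with the c-Jun E2 list for both classes. It was 5.09 points (3.82 to 6.36) with each tamoxifen list cut to the length of its E2 list. Within 5 groups of peak p it was 9.70 points (8.45 to 10.95), and among peaks of low input 8.68 points (7.41 to 9.94). Taken singly, a longer c-Jun list, stronger peaks or high input thus did not account for all of it. They were not removed together, and the use of the E2 list changes the treatment as well as the length. The difference depended on which c-Jun list was used, since the tamoxifen list for both classes gave 7.83 points against 3.65 with the E2 list. It was -0.54 points (-1.15 to 0.07) with the vehicle c-Jun list, and 1.64 points (-0.02 to 3.29) with all lists cut at 8-fold, which also counts as unique the ERα peaks with a partner under 8-fold and so does not measure the strong peaks of the same classes. Within the 5 groups of ERα peak p it was 11.8 points (9.17 to 14.4) in the weakest and 8.50 points (5.78 to 11.2) in the strongest. The lowest value was 6.36 points (3.56 to 9.16), in the group next to the strongest. What separates these settings was not tested, and an effect of tamoxifen on c-Jun at these sites stays open.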

How the results depend on the processing

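The settings with low input, a common p threshold, 6 lists at one length or one c-Jun list for both classes, and the comparison of classes unique to 1 ligand, were chosen only after the result was seen. For 31 results 175 alternatives were computed, of which 70 kept the value, 99 moved it beyond its interval or 1.5 times its count, and 6 reversed its sign, 4 of them by construction of the centring described below. Vehicle lists stayed shorter than treated lists in every setting that recounted peaks (8-fold, chromosomes left out, both input filters and the common p threshold). No paired analysis was possible because each group has 1 library. Start-site, motif and gene list alternatives were not run. Depth limits the weak peaks most, and intervals over many peaks are narrow, so small shifts count as moved. Where no cause is given below, the cause was not tested.

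At 8-fold over input or more, ERα peaks numbered 2149, 14372 and 14900 and c-Jun peaks 1043, 6476 and 7820 (vehicle, E2, tamoxifen), fewer by construction, and the c-Jun ratios to vehicle were 6.21 and 7.498. Both lists of an overlap were cut, so the shares below need a partner of 8-fold as well, unlike the counts of peaks with no partner of any fold. Vehicle peaks were in E2 for 99.9% (ERα) and 99.5% (c-Jun) and in tamoxifen for 99.95% and 99.7%. E2 peaks were in tamoxifen for 80.1% and 87.4%, and tamoxifen peaks in E2 for 77.2% and 72.4%. ERα peaks overlapped c-Jun for 7.72%, 21.99% and 25.8%, c-Jun peaks overlapped ERα for 15.9%, 48.7% and 49.1%, and the difference between classes unique to 1 ligand was 1.64 points.

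Without chromosomes 1, 17 and 20, vehicle peaks were in E2 for 95.4% (ERα) and 93.1% (c-Jun) and in tamoxifen for 95.7% and 93.5%, and ERα peaks overlapped c-Jun for 27.5%, 37.8% and 42.8%. Without the 1% of peaks with the highest input, vehicle peaks were in E2 for 91.0% and 89.5% and in tamoxifen for 90.9% and 89.7%. With input under 3 times background, these shares were 96.4%, 93.5%, 96.4% and 94.1%. In that setting E2 peaks were in tamoxifen for 77.0% and 78.7%, tamoxifen peaks in E2 for 72.0% and 67.9%, ERα peaks overlapped c-Jun for 25.8%, 37.0% and 41.9%, and c-Jun peaks overlapped ERα for 25.4%, 49.6% and 52.0%.

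Matched list lengths kept the peaks of best p. Within an antibody every list was cut to the vehicle length, 5955 (ERα) or 6084 (c-Jun) peaks. Between antibodies the longer list of a treatment was cut to the shorter. For the class difference each tamoxifen list was cut to the length of its E2 list. With these lengths, vehicle peaks were in E2 for 70.0% (ERα) and 68.9% (c-Jun) and in tamoxifen for 74.2% and 69.6%. c-Jun E2 peaks were in tamoxifen for 83.1%, c-Jun tamoxifen peaks in E2 for 83.1% and ERα tamoxifen peaks in E2 for 77.5%. ERα peaks overlapped c-Jun for 43.5% in E2 and 46.8% in tamoxifen, c-Jun peaks overlapped ERα for 44.1% and 47.3%, and the class difference was 5.09 points. With all 6 lists at the shortest length, ERα peaks overlapped c-Jun for 31.6% and 31.6%, and c-Jun peaks overlapped ERα for 31.7% and 31.8%.

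With 50% reciprocal overlap, a stricter rule by construction, vehicle peaks were in E2 for 63.2% and 75.4% and in tamoxifen for 64.8% and 72.4%. E2 peaks were in tamoxifen for 74.2% and 74.8%, tamoxifen peaks in E2 for 69.5% and 65.2%, ERα peaks overlapped c-Jun for 24.3%, 32.4% and 36.9%, and c-Jun peaks overlapped ERα for 23.8%, 42.3% and 44.9%. The log2 pileup ratios to vehicle were 1.60 for ERα in E2, 1.69 for ERα in tamoxifen and 1.02 for c-Jun in tamoxifen, and the class difference was 6.84 points. With centres within 100 bp, vehicle peaks were in E2 for 76.5% and 80.5% and in tamoxifen for 77.4% and 79.8%. In this setting E2 peaks were in tamoxifen for 71.8% and 72.4%, tamoxifen peaks in E2 for 67.3% and 63.1%, ERα peaks overlapped c-Jun for 23.4%, 31.5% and 35.8%, c-Jun peaks overlapped ERα for 22.9%, 41.2% and 43.5%, and the class difference was 6.17 points.

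Centring on the peaks held by all 3 lists of an antibody reversed the log2 ratios to vehicle to -0.00715 for ERα in E2, -0.00590 for ERα in tamoxifen, -0.00565 for c-Jun in E2 and -0.0107 for c-Jun in tamoxifen, and the c-Jun ratio of tamoxifen to E2 to -0.0335. For the 4 ratios to vehicle this follows by construction, since the median of nearly the same peaks is subtracted, so centring shows nothing about them. The class difference was 3.65 points with the c-Jun E2 list for both classes, 7.83 points with the tamoxifen list and -0.54 points with the vehicle list.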

Other observations

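All comparisons in this part were chosen only after the data were seen.

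ERα sites that differed between ligands were found among strong peaks as differences of level. Of 5480 ERα peaks shared by E2 and tamoxifen, with low input and at least 20-fold over input in either list, 549 (10.0%) were at least 2-fold higher in E2, 218 (3.98%) were at least 2-fold higher in tamoxifen and 4713 were within 2-fold. ERα was already called in vehicle at 39.2% (35.1 to 43.4%) of the sites higher in E2, at 47.2% (40.5 to 54.1%) of those higher in tamoxifen and at 72.3% (71.0 to 73.6%) of the others. Median ERα pileups per 10 M tags in E2 and tamoxifen were 45.0 and 17.1, 14.8 and 36.1, and 41.6 and 41.6 in the same order. Sites that differ are thus weaker with 1 ligand by selection. Stronger peaks were more often called in vehicle, and these classes were not compared at equal strength. The largest differences, chosen after their values were seen, included chromosome 19 from 46381187 to 46381955, with an ERα pileup per 10 M (mega) tags of 43.5 in E2 and 5.44 in tamoxifen, and chromosome 8 from 95049551 to 95049926, with 66.9 and 9.71. In the other direction were chromosome 17 from 7389623 to 7389850, with 6.54 in E2 and 41.2 in tamoxifen, and chromosome 22 from 43795990 to 43796291, with 17.3 and 75.7.

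Where c-Jun was called in both lists, its median level was slightly lower in tamoxifen at the strong sites higher in E2. At the sites higher in tamoxifen its ratio did not differ from that at the sites within 2-fold by more than the intervals. c-Jun was called at 38.5% (32.0 to 45.3%) of the sites higher in tamoxifen in the E2 list and at 53.7% (46.8 to 60.4%) in the tamoxifen list, while the sites higher in E2 held it at 57.2% (52.9 to 61.4%) and 53.4% (49.1 to 57.6%). The sites within 2-fold held it at 65.9% (64.5 to 67.2%) and 70.4% (69.1 to 71.7%). From the E2 to the longer tamoxifen c-Jun list, the share rose more at the sites higher in tamoxifen than at those within 2-fold, but from a lower start. The 2 lists were read at the same sites, and the difference between the rises was not tested. The median c-Jun log2 ratio of tamoxifen to E2 was -0.09 (-0.13 to -0.01) at 259 sites higher in E2, 0.15 (0.13 to 0.16) at 2912 sites within 2-fold and 0.16 (0.11 to 0.30) at 80 sites higher in tamoxifen. Over 10043 regions with both factors in both lists, the ERα and c-Jun log2 ratios had a Pearson correlation of 0.18, across regions and not across replicates. These regions were cut in 5 groups by the ERα change from E2 to tamoxifen, and the c-Jun median rose with it. It was 0.05 (0.04 to 0.07) in the 2015 regions where ERα fell most (median log2 ratio -0.70). In the 2007 regions where ERα rose most (median 0.69), it was 0.21 (0.19 to 0.23). A value above 0 is no sign of a c-Jun gain, since the median over all shared c-Jun peaks was 0.11, and -0.03 after centring.

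c-Jun peaks were gained both at ERα sites and away from them. Of the 18695 c-Jun peaks gained in E2, 47.4% (46.6 to 48.1%) overlapped no peak of any ERα list, as did 46.9% (46.2 to 47.5%) of the 22224 gained in tamoxifen. The number of c-Jun peaks rose 3.14 times in E2 and 3.58 times in tamoxifen at ERα sites, and 6.32 and 7.31 times away from them. This contrast in counts was not particular to c-Jun. The number of ERα peaks rose 3.12 and 3.37 times at c-Jun sites, and 14.1 and 14.95 times away from c-Jun sites. At c-Jun peaks also called in vehicle the median log2 ratio of E2 to vehicle was 0.91 (0.89 to 0.92) at ERα sites and 0.72 (0.70 to 0.75) away from them. For ERα peaks the order was the other way, at 1.68 (1.65 to 1.70) at c-Jun sites and 1.86 (1.79 to 1.91) away from them. Neither contrast was made at equal peak strength.

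Strong c-Jun sites with no ERα peak in any list included chromosome 18 from 19612334 to 19612726, with a c-Jun pileup per 10 M tags of 22.9 in vehicle, 43.9 in E2 and 38.3 in tamoxifen, and chromosome 15 from 93465033 to 93465409, with 17.7, 37.8 and 29.8.

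The input sample is labelled T47D in its description and MCF-7 in its cell line field. Its median level at peaks was 22.1 times background on chromosome 20 from 52000001 to 53000000, 11.05 times on chromosome 3 from 64000001 to 65000000 and 7.66 times on chromosome 1 from 116000001 to 117000000, against a median of 1.28 times over the 1959 windows with at least 20 peaks.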
